A study of Mus musculus with 12 samples.

How the data were processed

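The data are 12 arrays of total RNA from whole bone marrow flush, with 3 arrays in each of 4 groups defined by irradiation and treatment. The labels do not say whether the arrays of a group came from separate mice or pools, so p-values measure only the spread between these samples, which may in part be technical. Each irradiated group held arrays of both sexes by Xist and Y-linked genes, and so RNA of more than 1 mouse or pool. Per the labels' protocols, long bones were flushed with Trizol, RNA was cleaned on columns, and biotinylated cDNA was made from 100 ng of total RNA by whole-transcript amplification. Per the submitters' processing notes, the tools affy, RMA and limma were used, with no versions or roles given. The authors' deposited value table holds log2 values, a scale read from the values themselves and the name RMA, which stands for background correction, quantile normalization and median polish of array probes. The ranges of the arrays differ, and whether all were normalized together is not given in the sources used here. The genome build is not given in the sources used here, so no coordinates are printed.

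The table held 35556 rows. Of these, 21789 had exactly 1 gene symbol in the annotation table, 1621 had several and 12146 were not listed there. Rows with 1 symbol gave 19938 genes, the row with the highest mean over the arrays being taken for the 999 genes with several rows. Symbols were checked against RefSeq's mouse table of assembly GRCm38.p6 through the gene identifier, and 91 rows had no match and kept their symbol. Rows with several symbols or none were left out of the named results.

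All 12 arrays were fitted with limma 3.58.1 in R 4.3.3 as a model of 4 group means with 8 residual degrees of freedom, followed by empirical Bayes moderation with default settings. There were 7 contrasts: PTH against vehicle in each irradiation state, irradiation in each treatment, both averages, and the interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Before the data were examined, 23 gene lists of marrow cell types, bone cells and pathways were fixed, with 413 entries, of which 378 could be measured and 35 were not analysed here, Cdkn1a and Bglap among them. Lists were tested with limma's camera with a preset correlation of 0.01, again with a correlation estimated per list, and with fry, all adjusted over the 23 lists of a contrast. Fry asks whether the genes of a list move on balance one way, and does not compare the list with other genes.

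The genes named were chosen by a rule fixed before the data were examined. They were the 6 largest rises and 6 largest falls among genes past the threshold whose groups did not overlap, in each single contrast. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were taken and are said not to pass. Up to 4 members of each list with the smallest p, and 12 genes of bone and marrow biology, were also taken. Predicted genes, olfactory receptors, small RNAs and antigen receptor segments were passed over in the ranking. Xist, Kdm5d, Uty and Eif2s3y were also read as markers of sex, a use chosen after their values were seen.

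The fit was tested on simulated data for irradiation in vehicle mice, with 200 of 19938 genes changed in 10 simulations drawn from the real means and residual spreads. Of genes changed by a log2 of 0.5, 1 and 2, 13.9%, 66.1% and 95.6% were called, and 5.28% of all calls were false. For PTH in irradiated mice, a list shifted by -0.5 was called in 10 of 10 simulations and 0 of 220 unshifted lists were called, with genes drawn independently of each other. This does not measure false calls among correlated genes. Other splits of the real arrays in this comparison gave a median of 7 lists by the preset test. Alternatives covered the variance model, array weights, scaling, filters, row choice, the replicate number as a block, and leaving out each array. A term for sex, a fit without both arrays with a narrow range and a block in the irradiated groups alone were added after seeing the data. The labels do not say that replicate numbers pair the arrays, and in the irradiated groups the data do not settle it. There the 3 pairs with the same number had correlations of deviations from the group means of 0.144 to 0.57, against -0.509 to 0.396 for other numbers. Of these 6 arrays, 4 correlated best with their own number. Replicate 1 of both groups has the female pattern, so sex may be part of these correlations.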

Results

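Gene expression was measured in whole bone marrow flushed from the long bones of C57BL/6-type (B6) mice, on 12 whole-transcript microarrays. The 12 arrays formed 4 groups of 3, in which mice were nonirradiated or irradiated and then received vehicle or parathyroid hormone (PTH), a peptide hormone that acts on bone-forming cells and raises bone formation when given intermittently. Irradiation was sub-lethal, in 2 fractions of 310 cGy at 10 days of age. Treatment ran for 5 days, from day 11 to day 15, and marrow was taken at day 16. The design asks how irradiation of the marrow changes its expression and whether it changes the response to PTH. Values are log2 expression, and the number of arrays limits their precision: the median standard error of a difference between 2 groups was 0.166 over 19938 genes.

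Xist, the RNA that silences an X chromosome in female cells, and Kdm5d, a Y-linked gene, split the arrays by the sex of the mice. Of the 3 nonirradiated vehicle arrays, 0 had the female pattern, against 3 of the 3 nonirradiated PTH arrays. Each irradiated group held 1 female-pattern and 2 male-pattern arrays. Xist lay between 11.03 and 11.69 in the 5 female-pattern arrays and between 5.48 and 6.77 in the 7 male-pattern arrays. The arrays of nonirradiated vehicle replicate 3 and irradiated PTH replicate 3 had interquartile ranges of 2.63 and 2.66, against 2.999 to 3.14 for the other arrays. Irradiated PTH replicate 3 also lay apart from the rest on the first principal component, which held 39.6% of the variance.

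**Figure D1:**
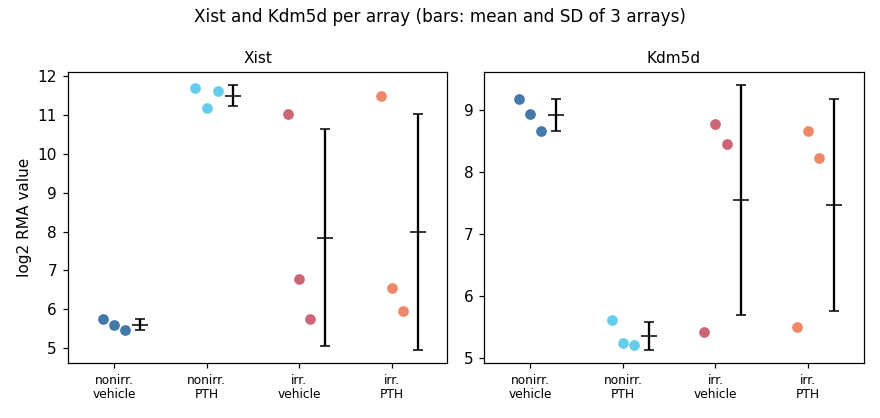
Log2 values of Xist and Kdm5d on each array, by group, with the mean and SD of 3 arrays. All 3 nonirradiated PTH arrays have high Xist and low Kdm5d, all 3 nonirradiated vehicle arrays the opposite, and each irradiated group holds 1 array with high Xist.

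Irradiation in vehicle-treated mice lowered B-lineage genes and raised adipocyte genes in the marrow 6 days later. Ms4a1, which encodes the B cell surface protein CD20, fell by 4.33 on the log2 scale (SE 0.193, adjusted p = 7.59e-07), from 10.02 ± 0.366 to 5.68 ± 0.0417 (SD, n = 3). Serpina3n, which encodes an acute-phase protease inhibitor, rose by 4.28 (SE 0.231, adjusted p = 3.61e-06), from 5.68 ± 0.0816 to 9.96 ± 0.146 (SD, n = 3). In limma's moderated test with Benjamini-Hochberg adjustment, 442 genes changed, 241 higher and 201 lower, and 242 of them by at least 2-fold. Of all genes, 18.8% had groups that did not overlap, where chance gives 10%. The balance of higher and lower genes turned with arrays centred on housekeeping genes (186 and 307), with quantile normalization repeated (268 and 329) and without nonirradiated vehicle replicate 3 (109 and 155) or irradiated vehicle replicate 1 (131 and 140). With sex as a term (151 and 153) or without both narrow-range arrays (253 and 257), both chosen after seeing the data, it was close to even. The other large rises were Ccl12, a monocyte-attracting chemokine (3.68), Lipg, endothelial lipase (3.48), Abhd6, a lipid hydrolase (3.02), the interferon-inducible gene Ifi205 (2.86) and the cytochrome P450 gene Cyp2f2 (2.79). The other large falls were Cpm, carboxypeptidase M (-3.01), Cd72, a B cell coreceptor (-2.83), Il1b, the cytokine interleukin-1 beta (-2.74), Iftap (-2.59) and Spib, a transcription factor of B cells and plasmacytoid dendritic cells (-2.57). Iftap neighbours Rag2 and Rag1 in the reference table, and its dimmer array row changed by only -0.21. All 12 of these genes kept their call in every fit that left out 1 array. Of the arrays compared, 0 of 3 nonirradiated and 1 of 3 irradiated ones had the female pattern.

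Of 19 measured B-lineage genes, 16 fell in irradiated vehicle mice (17 adjusted over the list alone) and 0 rose, with a median log2 change of -1.78. Besides Ms4a1 and Cd72, Fcrla, a B cell Fc receptor-like gene, fell by 2.39 and Il7r, the interleukin-7 receptor of B and T cell precursors, by 2.19. Of 16 adipocyte genes, 9 rose (14 adjusted over the list alone), with a median of 1.21. Cidec and Plin1, which coat lipid droplets, rose by 2.33 and 1.36, Fabp4, a fatty acid carrier, by 1.41, Scd1, a fatty acid desaturase, by 1.59 and Adipoq, which encodes the adipocyte hormone adiponectin, by 1.70. The adjusted p of limma's camera test with an estimated correlation was 0.00765 for the B-lineage list and 0.00264 for the adipocyte list, and at most 0.0245 and 0.00979 without any 1 array. The call for Adipoq ended without nonirradiated vehicle replicate 2 or 3 or irradiated vehicle replicate 2 or 3, and its highest adjusted p over all alternatives was 0.0651.

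**Figure D2:**
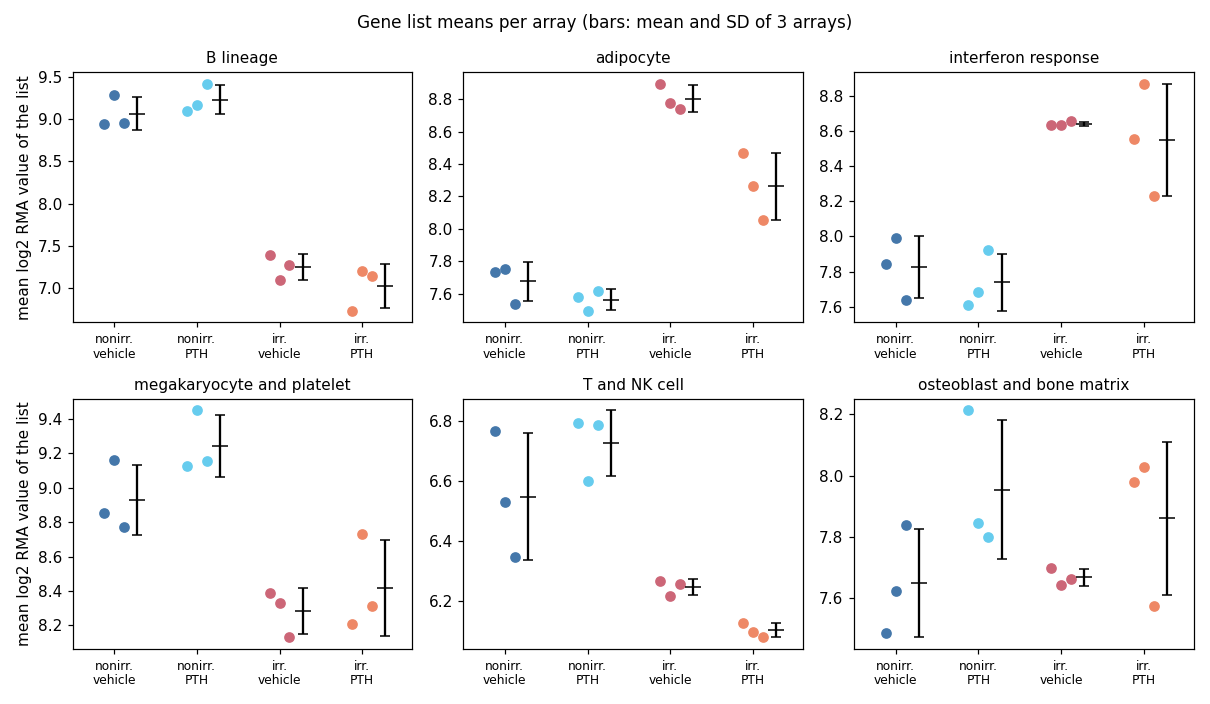
Mean log2 value of the measured genes of 6 lists on each array, by group, with the mean and SD of 3 arrays. B-lineage means were 9.06 and 9.23 in nonirradiated vehicle and PTH mice and 7.25 and 7.02 in irradiated ones, while adipocyte means were 7.68, 7.56, 8.80 and 8.26 in the same order.

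Single members of other lists also passed in irradiated vehicle mice. Of 18 interferon response genes, 5 rose and 0 fell (15 rose adjusted over the list alone), among them Oas1a (1.33), Rtp4 (1.35), Ifit1 (1.39) and Oasl2 (1.59). Of 11 megakaryocyte and platelet genes, 2 fell, Mmrn1, multimerin of platelet granules (-1.41), and Clec1b, a platelet receptor (-0.99). Of 17 p53 target genes, 2 rose, Eda2r (1.12) and Tnfrsf10b (0.77), and of 20 inflammatory genes Il1b fell while Cxcl9, an interferon-gamma-induced chemokine, rose by 1.52. All of these lists lay past the camera test with its preset correlation, with adjusted p = 0.119 for each with an estimated correlation. Of 13 T and NK cell genes, Cd2 fell by 1.86 (list adjusted p = 0.187 with an estimated correlation). Monocyte and macrophage, endothelial and stromal lists had positive medians of 0.26, 0.40 and 0.20, with adjusted p = 0.486 for each with an estimated correlation, and among them Marco (0.71) and Cd5l (1.66), both macrophage genes of the scavenger receptor cysteine-rich family, rose. Marco, Cd5l and Tnfrsf10b kept their calls in only 3 of 12 fits that left out 1 array, Oasl2 in 7, Ifit1 in 9 and Clec1b in 11. With sex as a term, Marco, Cd5l, Tnfrsf10b and Oasl2 did not pass.

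The remaining 13 lists, covering erythroid, neutrophil, dendritic cell, eosinophil and mast cell, stem cell, osteoblast, osteoclast, chondrocyte, muscle, cell cycle, PTH and cAMP response, growth factor and housekeeping genes, had adjusted p from 0.0752 to 0.988 by the preset test in vehicle mice. Within the dendritic cell list the plasmacytoid marker Siglech (-1.53) and Cd209a (-1.30) fell, while Xcr1, a marker of conventional dendritic cells, rose by 1.52. Car1, an erythroid carbonic anhydrase (-1.25), Angpt1, a stem cell niche ligand (-0.82), and the cAMP-related genes Pde4b (-0.86) and Rgs2 (-0.98) fell. Mmp13, a collagenase of bone (1.10), and Fgf23, a phosphate-regulating hormone of bone (2.09), rose. Of these, Rgs2 kept its call in 4 of 12 fits that left out 1 array, Angpt1 and Fgf23 in 9, Car1 in 10 and Xcr1 in 11, and Rgs2 did not pass with sex as a term. The osteoblast genes Col1a1 (0.04) and Pth1r, the PTH receptor (0.23), the osteoclast gene Acp5 (-0.21), and Il6 (0.77), Tnfsf11 (0.37), Cxcl12 (0.10), Kitl (0.40), Ccl2 (0.37) and Vegfa (0.48) did not pass. The count of 442 moved by over 1.5 times without nonirradiated vehicle replicate 2 (289) or 3 (264), irradiated vehicle replicate 1 (271), 2 (211) or 3 (231), or irradiated PTH replicate 3 (762), and with array weights (1149). With sex as a term, chosen after seeing the data, it was 304.

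The irradiation effect in PTH-treated mice had the same main features. Ms4a1 fell by 4.29 (SE 0.193, adjusted p = 8.52e-07) and Serpina3n rose by 3.51 (SE 0.231, adjusted p = 3.54e-05). In all, 485 genes changed, 138 higher and 347 lower, 254 of them by at least 2-fold. Ccl12 (3.46), Ankrd36 (3.16, and 2.21 on its dimmer array row), Lipg (3.07), Ifi205 (2.65) and Cyp2f2 (2.56) were the next largest rises, and Cpm (-3.40), Cd72 (-3.08), Spib (-2.93), Iftap (-2.85, and 0.03 on its dimmer row) and Rag1, a recombinase of developing lymphocytes (-2.80), the next largest falls. Cyp2f2 lost its call without nonirradiated PTH replicate 1 or 2, and its highest adjusted p over all alternatives was 0.0922. Of the arrays compared, 3 of 3 nonirradiated and 1 of 3 irradiated ones had the female pattern. Between vehicle and PTH mice, 85 genes were higher with irradiation in both and 170 lower in both, and 0 genes were called in opposite directions. Independent lists of these sizes would share 1.67 and 3.5. Both contrasts use the same variance estimate of each gene, and genes are correlated, so these expected numbers are no test.

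Of 19 B-lineage genes, 17 fell in irradiated PTH mice, with a median of -2.26 and examples in Il7r (-2.58), Cd79b, part of the B cell receptor (-2.59), and Fcrla (-2.51). Of 16 adipocyte genes, 4 rose (12 adjusted over the list alone), Cidec (1.86), Scd1 (1.78), Fabp4 (1.28) and Plin1 (0.76), with a list median of 0.57. Of 13 T and NK cell genes, 3 fell, Cd2 (-2.09), Cd3e (-0.90) and Cd8a (-0.88). These 3 lists held with an estimated correlation, at adjusted p = 0.00815, 0.0106 and 0.0251. The T and NK cell list missed the threshold without nonirradiated PTH replicate 3 (0.0819), irradiated vehicle replicate 3 (0.0506) or irradiated PTH replicate 1 (0.0622) or 2 (0.0639). Gp9, Cd8a and Cd3e kept their calls in 3, 6 and 9 of 12 fits that left out 1 array, and none of these 3 genes passed with sex as a term. Of 18 interferon response genes, 6 rose, led by Oas1a (1.77), Ifit1 (1.83), Rtp4 (1.49) and Rsad2 (1.33), with adjusted p = 0.0951 for the list with an estimated correlation. Mmrn1 (-1.44), Clec1b (-1.10) and Gp9 (-0.76) of the 11 megakaryocyte and platelet genes fell (adjusted p = 0.0814 with an estimated correlation).

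Other genes that passed in irradiated PTH mice were Il6, a cytokine that PTH is known to induce in bone (1.29), Ccl7 (1.08), Il1b (-2.34), Eda2r (1.03), Polk (0.80), Marco (0.92), Ucma (0.81), Fgf23 (1.67), Lef1 (-1.62), Pde4b (-1.12), Rgs2 (-0.95), Car1 (-1.27), Prss34 (-0.67) and the stem and progenitor genes Kit (-1.27) and Meis1 (-1.01). Fgf23 kept its call in 2 of 12 fits that left out 1 array, Rgs2 in 3, Ucma and Polk in 4, Prss34, Meis1 and Ccr9 in 8, Eda2r in 9, Kit, Car1 and Il6 in 10 and Lef1 in 11. With sex as a term, Il6, Ccl7, Eda2r, Polk, Marco, Ucma, Lef1, Car1, Prss34, Kit, Meis1 and Ccr9 did not pass. The highest adjusted p of these genes over all alternatives ran from 0.082 for Car1 to 0.287 for Ucma. It was 0.111 for Ccl7, 0.0928 for Marco and 0.141 for Il6. With only the groups compared, Ccl7, Polk, Ucma, Fgf23, Rgs2, Prss34, Meis1 and Ccr9 did not pass. The Il6 change did not pass as a difference between treatments, with an interaction of 0.52 (SE 0.335, adjusted p = 0.732). Siglech (-1.58), Cd209a (-1.59) and Ccr9 (-1.55) fell in the dendritic cell list. The neutrophil (median -0.38), dendritic cell (-0.34), stem cell (-0.31), chondrocyte (0.15), p53 target (0.30) and inflammatory (0.12) lists lay past the preset camera test, with adjusted p of 0.362, 0.377, 0.508, 0.329, 0.121 and 0.0951 with an estimated correlation. Adipoq (1.02), Ccl2 (0.60), Tnfsf11 (0.37), Kitl (0.19), Vegfa (0.08), Pth1r (0.00), Cxcl12 (-0.38), Acp5 (-0.41) and Col1a1 (-0.62) did not pass. The count of 485 moved by over 1.5 times without nonirradiated PTH replicate 1 (225), 2 (266) or 3 (249) or irradiated PTH replicate 1 (283), with array weights (1148) and with only the groups compared (232). With sex as a term, chosen after seeing the data, it was 200.

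**Figure D3:**
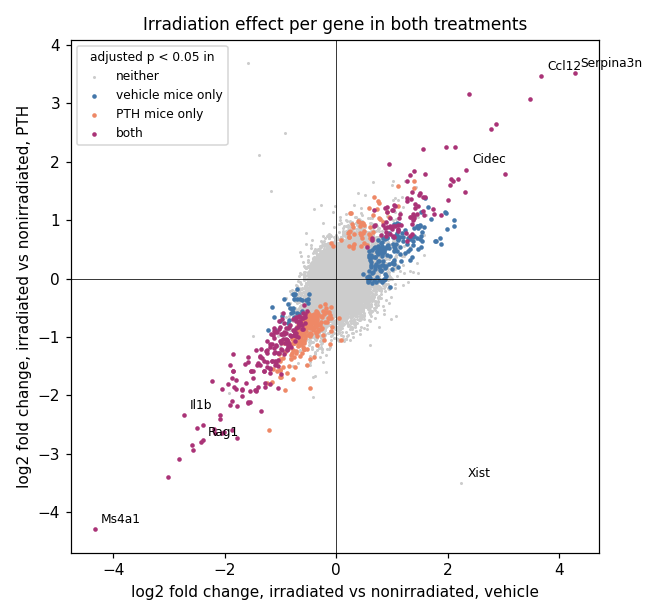
Log2 fold change of each gene with irradiation in vehicle mice (horizontal) and in PTH mice (vertical), coloured by the treatments in which the adjusted p was under 0.05. Ms4a1 lies at -4.33 and -4.29 and Serpina3n at 4.28 and 3.51, and Xist, whose split follows the sex of the mice, lies off the diagonal.

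Averaged over both treatments, irradiation changed 1216 genes, 500 higher and 716 lower, and 705 and 688 without irradiated PTH replicate 3. The lists that held with an estimated correlation were B lineage (17 of 19 lower, median -1.99, adjusted p = 0.00434), T and NK cell (4 of 13 lower, adjusted p = 0.0443), megakaryocyte and platelet (6 of 11 lower, adjusted p = 0.0443), adipocyte (12 of 16 higher, adjusted p = 0.00337), interferon response (11 of 18 higher, adjusted p = 0.0443) and inflammatory (4 of 20 higher and 1 lower, adjusted p = 0.0443). The 4 lists at 0.0443 were close to the threshold: with each array left out in turn their adjusted p reached 0.0765 for T and NK cell, 0.0898 for megakaryocyte, 0.0898 for interferon and 0.101 for inflammatory genes, and the threshold was missed in 9, 11, 11 and 12 of the 12 fits respectively. The B-lineage and adipocyte lists stayed at or under 0.0132 and 0.0095. Stem and progenitor, endothelial and p53 target lists lay past the preset test, with adjusted p = 0.623, 0.627 and 0.0512 with an estimated correlation. The count was 748 when a fold of at least 1.5 was also required, and 2517 with array weights. Across 19938 genes, which are not independent replicates, the irradiation effects in vehicle and PTH mice had Pearson r = 0.491 and Spearman rho = 0.241. Relabelling the arrays within each treatment gave r from -0.545 to 0.623 in 100 draws.

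PTH in irradiated mice lowered the adipocyte list, the only list of 23 that held with an estimated correlation in this comparison. All 16 measured members had negative changes, with a median log2 change of -0.57, and the list mean was 8.26 ± 0.206 with PTH and 8.80 ± 0.0832 with vehicle (SD, n = 3). The list had an adjusted p of 1.26e-11 by the preset camera test, 0.0157 with an estimated correlation and 0.00915 by fry. The same irradiated vehicle arrays enter the rise of this list with irradiation, so the 2 differences are not independent. Adjusted over the list alone, 8 of the 16 genes were lower, and 0 over all genes tested. Members with the smallest p were Plin1 (-0.73, SE 0.130), Cidec (-1.06, SE 0.247), Adig, which is expressed in adipocytes (-0.64), and Car3, a carbonic anhydrase of fat and muscle (-0.95), each with adjusted p = 0.844. The estimated-correlation p rose to 0.112 without irradiated PTH replicate 2, 0.0937 without irradiated vehicle replicate 3 and 0.140 with dim genes left out, and lay from 0.00485 to 0.140 over all alternatives.

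Single genes did not pass in this comparison: limma called 0 of 19938 genes between PTH and vehicle in irradiated mice, where 759 had an unadjusted p under 0.05 and chance would give 997. With the replicate number as a block in these 2 groups, chosen after seeing the data, 2 adipocyte genes were lower, Aqp7, a glycerol channel (-1.20, adjusted p = 0.0400), and Cidec (-1.06, adjusted p = 0.0474). Whether the numbers pair these arrays is not settled. The genes with the smallest p, none of which passed, were Jchain, the joining chain of secreted antibodies (0.997), Fabp7 (0.78) and Fam131a (0.49) on the higher side, and Plin1, Slc6a13, an amino acid transporter (-0.80), and Hcar1, a lactate receptor of adipocytes (-1.01), on the lower side. Among osteoblast and bone matrix genes, Ibsp (0.75), Postn (0.80), Dmp1 (0.69) and Mepe (0.29) had the smallest p, and among osteoclast genes Slc9b2 (0.87) and Atp6v0d2 (0.70). The osteoblast, osteoclast and chondrocyte lists lay higher, and the B-lineage, dendritic cell, stromal, growth factor and eosinophil lists lower, by the preset test, with adjusted p of 0.532 to 0.66 with an estimated correlation. Preset calls held in 7 of 12 fits without 1 array for eosinophil, 9 for growth factor and osteoclast, 10 for osteoblast, dendritic cell and stromal, and 11 for B-lineage and chondrocyte lists. The stromal mean nearest 0 in these fits was -0.007. With the replicate number as a block in these 2 groups, the osteoclast list lost its preset call (adjusted p = 0.0562). The endothelial (adjusted p = 0.0284) and monocyte and macrophage (adjusted p = 0.0392) lists were then called as lower by the preset test. With that block and an estimated correlation, these lists had adjusted p of 0.66 and 0.649 and were not called. The values for the other genes followed throughout were Il6 0.35, Acp5 0.25, Ccl2 0.03, Pth1r -0.04, Tnfsf11 -0.07, Kitl -0.21, Cxcl12 -0.30, Vegfa -0.30, Col1a1 -0.34 and Adipoq -0.50.

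PTH in nonirradiated mice was compared between 3 female-pattern arrays with PTH and 3 male-pattern arrays with vehicle, so the treatment and the sex of the mice cannot be told apart here. Limma called 0 of 19938 genes, with 356 at an unadjusted p under 0.05, where chance would give 997. The genes with the smallest p were Xist (5.89), Aldh1a2, a retinoic acid-making enzyme (1.20), and Dmp1, a matrix protein of osteocytes (1.01), on the higher side, and Kdm5d (-3.57), Mageb3 (-0.53) and Eif5a2 (-0.54) on the lower side, each with adjusted p = 0.9996 or more. Both irradiated groups hold arrays of both sexes, which widens the spread of Xist and Y-linked genes in the fit of all 4 groups. When only these 2 nonirradiated groups were fitted, 4 genes passed, Xist (adjusted p = 4.2e-06) and the Y-linked genes Kdm5d, Eif2s3y (-5.02) and Uty (-3.58). By the preset camera test 10 lists lay apart: osteoclast (median 0.37), megakaryocyte (0.27), osteoblast (0.29), neutrophil (0.23), endothelial (0.18), stromal (0.11), B-lineage (0.15), T and NK cell (0.18) and dendritic cell (0.20) lists higher, and adipocyte (-0.07) lower. Their adjusted p was 0.478 to 0.592 with an estimated correlation. Of these lists, only megakaryocyte kept its preset call without each array and with sex as a term, chosen after seeing the data. The osteoclast median was 0.15 without nonirradiated vehicle replicate 1 (preset adjusted p = 0.108) and 0.02 with sex as a term (0.390).

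Averaged over irradiation, the adipocyte list was lower with PTH (median -0.31, 1 of 16 members above 0, adjusted p = 0.00374 with an estimated correlation). Its mean difference was -0.54 in irradiated mice and -0.11 in nonirradiated mice. By exact permutation of list means, chosen after seeing the data, the average had an adjusted p of 0.345. The nonirradiated arrays in this average differ in sex between treatments. Limma called 0 genes, with 252 at an unadjusted p under 0.05. Scd1 (-0.73), Cidec (-0.83) and Plin1 (-0.43) had the smallest p in this list. By the preset test the osteoblast (median 0.15), osteoclast (0.25) and megakaryocyte (0.21) lists were higher and the muscle (-0.22) and interferon response (-0.06) lists lower, with adjusted p of 0.199, 0.385, 0.286, 0.832 and 0.832 with an estimated correlation. The muscle and interferon lists kept their preset calls in 8 and 5 of 12 fits that left out 1 array, with means nearest 0 of -0.08 and -0.009. Dmp1 (0.85), Ibsp (0.57), Postn (0.62), Slc9b2 (0.68) and Atp6v0d2 (0.62) were the bone genes with the smallest p, and none passed over all genes. The PTH and cAMP response list had a median of 0.04 and an adjusted p of 0.416.

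The interaction asks whether the PTH response differed between irradiated and nonirradiated mice. In nonirradiated mice that response compares 3 female-pattern PTH arrays with 3 male-pattern vehicle arrays, while the irradiated groups are balanced in sex. A difference between the responses therefore cannot be told apart from sex. Limma called 0 of 19938 genes, with 1094 at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were Mageb3 (0.70), Serpinb1c (0.68) and Iqca (0.69, with smaller values on its other array rows) on the positive side and Kcnk5, a potassium channel (-0.88), Plekhf1 (-0.86) and Adh1, an alcohol dehydrogenase (-0.80), on the negative side, each with adjusted p = 0.732. The adipocyte list had a median interaction of -0.45, with an adjusted p of 0.00252 by the preset test and 0.486 with an estimated correlation. Its mean of -0.43 was -0.21 with arrays centred on the housekeeping list and -0.20 with sex as a term. Across genes, the PTH effects in nonirradiated and irradiated mice had Pearson r = -0.393 and Spearman rho = -0.423, and 25 of 100 relabellings within irradiation state gave an r at least as large in size. In alternatives chosen after seeing the data, this r turned direction to 0.352 with sex as a term, where the effects share arrays. It was near 0 without both arrays with a narrow range, at 0.00483 (Spearman rho -0.0645). It was also -0.115 without irradiated PTH replicate 3, -0.16 without nonirradiated vehicle replicate 1 and -0.196 without nonirradiated PTH replicate 2, so its size and direction depend on the fit.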

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

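All tests of explanations in this part were chosen after the results were seen, except the test of other splits and the correlation across genes for the sex of the mice.

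In the interaction between PTH and irradiation, 10 lists differed from the other genes by limma's camera with a preset correlation, and 0 with an estimated correlation. By fry, the test against no change, 0 lists passed. Mean log2 interactions were -0.39 for B lineage, -0.32 for T and NK cell, -0.43 for neutrophil, -0.50 for dendritic cell, -0.37 for eosinophil, basophil and mast cell, -0.43 for adipocyte, -0.30 for stromal, -0.31 for endothelial, -0.27 for growth factor and 0.20 for chondrocyte genes. These sizes depend on single arrays: without 1 array the values nearest 0 were -0.25 for B lineage, -0.28 for neutrophil, -0.29 for dendritic cell, -0.15 for stromal, endothelial and growth factor, and 0.10 for chondrocyte genes, and T and NK cell, eosinophil and growth factor lists kept their call in 6, 5 and 6 of 12 such fits. The housekeeping list itself had -0.22. With arrays centred on it, all 10 lists kept their call, with B lineage at -0.18, growth factor at -0.06 and chondrocyte genes at 0.41. Centring shifts all genes of an array alike and camera compares a list with other genes, so it could hardly change these calls. Chondrocyte (0.17), stromal (-0.12), endothelial (-0.06) and growth factor (-0.04) lists lost their call with sex as a term, and without both arrays with a narrow range dendritic cell, eosinophil, endothelial and growth factor lists did, both alternatives chosen after seeing the data. As many lists were called in 5 of 100 splits of the arrays within irradiation state, the real one included, with a highest other count of 11. Chance could therefore not be excluded. Sex could not be excluded either, since all nonirradiated PTH arrays have the female pattern and all nonirradiated vehicle arrays the male one.

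Some rows without a single gene symbol, which were left out of the named results, also differed with irradiation. When all 35556 rows were tested, 51 of these 13767 rows passed in vehicle mice, 24 higher and 27 lower, and 80 passed in PTH mice, 27 higher and 53 lower. These are smaller shares than the 442 and 485 of 19938 genes called in the main fit.

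The adipocyte list was lower with PTH in irradiated mice. The tables argue against the array with a narrow range, since without irradiated PTH replicate 3 the list mean still differed by -0.44, beyond the larger SD within groups of 0.145. Each irradiated group held 1 female-pattern and 2 male-pattern arrays, a balance that argues against the sex of the mice. The difference was -0.60 within the 4 male-pattern arrays, with a standard error of 0.105, and -0.43 between the 2 female-pattern arrays. The stromal and endothelial lists also lay lower with PTH, at -0.15 and -0.16, and the osteoblast list higher, at 0.19. The smallest gap between these lists and the adipocyte list was 0.38, with a standard error of 0.135. That gap argues against a lower yield of connective tissue that lowers all these lists alike. It cannot speak to a partly lower yield or to an unequal loss between these cell types. The irradiated vehicle arrays serve in this comparison and in the one of irradiation, which leaves their own deviation open, beside an effect of PTH on marrow fat as a hypothesis.

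The nonirradiated PTH and vehicle groups differed in Xist and Y-linked genes. Sex of the mice accounts for these genes: between irradiated PTH and vehicle, Xist differed by 0.45 for the female-pattern arrays and by -0.00223 for the means of the male-pattern arrays, of which single arrays differed by up to 0.82. For the other 19930 genes the female against male difference within irradiated groups correlated with the PTH difference at r = 0.272, where the 8 other choices of 1 array per irradiated group gave -0.423 to 0.378. For those genes sex and PTH cannot be told apart, because all PTH arrays of nonirradiated mice have the female pattern and all vehicle arrays the male one.

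Cell type lists moved apart with irradiation. A loss of B-lineage cells alone would raise all other lists alike, yet the gap between the megakaryocyte and adipocyte lists was -1.53 in PTH mice and -1.78 in vehicle mice, with a standard error of 0.194. These 2 lists were chosen after they were seen to move in opposite directions, so the gap is no independent test. Sex would turn the direction between treatments, because irradiated groups held more females than their controls in vehicle mice and fewer in PTH mice. Of the 442 genes called in vehicle mice, 97.1% had the same sign in PTH mice. Without both arrays with a narrow range, 83.0% of the 1216 genes called for irradiation were called the same way, and a change of cell makeup or of expression within cells stays open as a biological hypothesis.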

How the results depend on the processing

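Of the alternatives, sex as a term, leaving out both narrow-range arrays, the block in the irradiated groups alone, exact permutation of list means and the correlation of irradiation effects were chosen after seeing the data. Counts of 0 for PTH stayed 0 under the alternatives run, except 4 genes in nonirradiated mice with only the groups compared, 2 in irradiated mice with a block there, and 1 gene, Cidec (-1.22, adjusted p = 0.0104), in the PTH average with sex as a term. That fit estimates the sex effect from irradiated arrays only. For interaction and averages, a fit of only the groups compared is the same fit and was not run. Array weights gave 1149, 1148 and 2517 genes for irradiation in vehicle mice, in PTH mice and on average. In PTH mice, only the groups compared gave 232 and sex as a term 200, and on average a fold of at least 1.5 gave 748. Leaving out 1 array gave 211 to 762 genes in vehicle mice, 225 to 531 in PTH mice and 822 to 1393 on average, where fewer arrays in the groups compared is part of the alternative's construction. Centring on housekeeping genes moved the median of all genes to -0.155 in vehicle mice and 0.159 for PTH in irradiated mice, and the split in vehicle mice from 241 higher and 201 lower to 186 and 307. Leaving out nonirradiated vehicle replicate 3 gave 109 higher and 155 lower.

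Lists called fell to 0 with an estimated correlation and by fry for PTH in nonirradiated mice (5 with sex as a term) and for the interaction (1 with dim genes left out), and to 1 by both for PTH in irradiated mice (5 with dim genes left out) and the PTH average. For irradiation they were 2 in vehicle mice and 3 in PTH mice with an estimated correlation, 7 in PTH mice by fry, and on average 14 without both narrow-range arrays. Leaving out 1 array gave 4 to 10 lists for PTH in nonirradiated and 7 to 12 in irradiated mice, 7 to 13 and 9 to 15 for irradiation in vehicle and PTH mice, 6 to 11 for the interaction, and 4 to 8 and 9 to 13 for the averages of PTH and irradiation. The 4 for PTH in nonirradiated mice came without nonirradiated vehicle replicate 1, the 4 for the PTH average without irradiated vehicle replicate 3, and 6 for the interaction without nonirradiated vehicle replicate 2, nonirradiated PTH replicate 3 or irradiated PTH replicate 1. With sex as a term, the stromal and endothelial lists turned for PTH in nonirradiated mice, to mean changes of -0.0263 and -0.095. The correlation of PTH effects was -0.502 to -0.115 without 1 array (-0.115 without irradiated PTH replicate 3, -0.16 without nonirradiated vehicle replicate 1, -0.196 without nonirradiated PTH replicate 2), -0.206 over genes with an unadjusted p under 0.05, near 0 at 0.00483 (Spearman rho -0.0645) without both narrow-range arrays, and turned to 0.352 with sex as a term, where the effects share arrays. That of irradiation effects was 0.342 to 0.689 without 1 array, 0.739, 0.705 and 0.61 in the same settings. The cause was not tested for these changes. Of called genes named by the rule, 28 of 40 in vehicle mice and 31 of 47 in PTH mice kept their call without each array, and 0 turned direction.

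The replicate number as a replicate block gave 500 genes in vehicle mice, 672 in PTH mice, 1407 on average and 0 for PTH and the interaction, and moved no count by over 1.5 times. Over all groups the numbers do not pair the samples: 10 of 18 pairs with the same number had a correlation of deviations over 0.1, from -0.651 to 0.596, against -0.597 to 0.628 for other numbers. In the irradiated groups alone, same-number correlations (0.144 to 0.57) overlap those for other numbers (-0.509 to 0.396), so pairing is not settled there. The block in these groups gave 2 genes and 10 lists for PTH. By the preset test it ended the call of the osteoclast list, added the endothelial and monocyte lists, and changed no other list call. With an estimated correlation in camera no list call changed, and the endothelial and monocyte lists had adjusted p of 0.66 and 0.649. Signal over background on each array was not used here.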

Other observations

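Tests of other splits were planned before their results were seen, and the exact permutation tests of list means were chosen after seeing the data.

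Osteoblast list means with PTH were 0.30 and 0.19 higher in nonirradiated and irradiated mice. Without nonirradiated PTH replicate 1 the first was 0.17, and the second was 0.11 without irradiated PTH replicate 2 and 0.34 without irradiated PTH replicate 3. The osteoclast list mean was 0.16 higher in irradiated mice, 0.01 without irradiated PTH replicate 2, 0.04 without replicate 1 of that group, 0.44 without its replicate 3, and 0.10 without irradiated vehicle replicate 3. On average over both states it was 0.25 higher, and 0.39 without irradiated PTH replicate 3 (adjusted p = 0.0593 with an estimated correlation, from 0.0593 to 0.981 over the fits without 1 array). That mean was 0.12 with sex as a term, chosen after seeing the data, and its call by the preset test was lost (adjusted p = 0.0608). The osteoblast and bone matrix list mean was 0.25 higher with PTH on average over both states (exact permutation p = 0.055, adjusted over the lists 0.632, 2-sided). The adipocyte list mean was lower by PTH on average, at -0.33 (exact permutation p = 0.015, adjusted over the 23 lists 0.345). For irradiation on average, the B-lineage, T and NK cell, megakaryocyte, adipocyte, p53 target, interferon and inflammatory lists each had an exact permutation p of 0.005, the smallest that 400 relabellings can give, and 0.0164 adjusted over the lists. Single contrasts cannot go below 0.1 in this test. Stem and progenitor genes had a mean change of -0.27 (exact permutation p = 0.01, adjusted 0.0288), with an adjusted p of 0.623 by camera with an estimated correlation.

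Other splits of the arrays tested whether chance can be excluded. For irradiation averaged over treatment, 1 of 100 splits, the real one, gave as many genes, 1216 against at most 95 in the others. The other splits mix irradiated and nonirradiated arrays, which widens their spread, so 95 is not the count expected without an effect. The rank of 1 in 100 argues against chance. Single contrasts have 10 splits, too few for a share under 0.05. The real and highest other counts of genes were 442 and 0 for irradiation in vehicle mice and 485 and 0 in PTH mice, with 1 of 10 splits as large in each. They were 0 and 0 for PTH in nonirradiated and in irradiated mice, with 10 of 10 as large. For the interaction and the PTH average, with 0 genes, all 100 of 100 splits were as large, and the highest other counts were 1 and 0. Where the real count is 0, every split is as large by construction, so these shares test nothing.

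Counts of lists by the preset camera test were less specific to the real groups. In single contrasts, the real and highest other counts were 10 and 10 for PTH in nonirradiated mice (2 of 10 splits as large), 9 and 10 in irradiated mice (2 of 10), 10 and 7 for irradiation in vehicle mice (1 of 10) and 11 and 13 in PTH mice (4 of 10). For the averages, 52 of 100 splits called as many lists as the 6 for PTH, and 32 of 100 as many as the 9 for irradiation, with highest other counts of 13 and 12, so chance could not be excluded for either count.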
